A study of Homo sapiens with 10 samples.

How the data were processed

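Gene expression was measured in IMR90 cells, a strain of human fetal lung fibroblasts, on Affymetrix U133 Plus 2.0 arrays. The 10 arrays formed 5 groups of 2, per the labels: untreated growing cells, and cells infected with retroviruses carrying Ras and a hairpin against luciferase (shLuc), RB (shRB), E2F7 (shE2F7) or both RB and E2F7 (shRB-E2F7). Infected cells were selected with puromycin at 2 ug/ml for 2 days and hygromycin B at 100 ug/ml for 3 days, and RNA was taken 7 days after the end of the puromycin selection. Which Ras gene was used, the hairpin sequences and whether replicates were separate infections are not given in the sources used here.

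The deposited values were log2 intensities per probe set, made by the authors with GCRMA, a method that subtracts background by probe sequence and normalizes the arrays together, whose version is not given in the sources used here. The table held 54613 probe sets, of which 41091 carried 1 gene symbol, 1801 several and 11721 none. Symbols were compared with a RefSeq table (assembly GRCh38.p14) through their Entrez identifiers; none needed an update, and 54 probe sets had an identifier that the table lacked. No coordinates were used. For each of the 19775 genes with a probe set of its own, the probe set with the highest mean over the 10 arrays was taken. Genes above a log2 value of 4 in at least 2 of the 10 arrays were tested, which kept 10144 genes and left out 9631. GCRMA gives low values for transcripts near background, so the size of a change that starts below log2 4 is uncertain and is given on the log2 scale. The number of arrays limits the precision. The table held 0 control probe sets of the array maker, so a check of RNA integrity from them was not possible.

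Differential expression was computed in R 4.3.3 with limma 3.58.1. All 10 arrays entered 1 linear model with a mean per group, which left 5 residual degrees of freedom, and eBayes added 7.19 prior degrees of freedom. Tests were two-sided, p values were adjusted by Benjamini-Hochberg over the 10144 genes, and a gene was called at an adjusted p under 0.05. The 8 comparisons were shLuc against growing, each hairpin group against shLuc, shRB-E2F7 against shRB, shE2F7 and growing, and the interaction, which is the change of shRB-E2F7 against shRB less the change of shE2F7 against shLuc. Changes are log2 differences of group means with the standard error of the model (SE), and group means have their standard deviation (SD), over n = 2 arrays per group.

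A total of 24 gene lists was fixed: DNA replication and S-phase E2F targets, G2/M and mitosis, the E2F and RB families, homologous recombination and DNA repair, p53 targets, CDK inhibitors, cytokines and chemokines of the senescence-associated secretory phenotype (SASP), matrix proteases and inhibitors, IGF-binding proteins, collagens and fibrillar matrix, myofibroblast and TGF-beta targets, RAS-ERK targets and feedback, senescence-associated chromatin and nuclear envelope, replication-dependent histones, lysosome, interferon-stimulated genes, cholesterol biosynthesis, the unfolded protein response, glycolysis, cytosolic ribosomal proteins, pro-apoptotic E2F and p53 targets, and markers of epithelial cells, endothelial cells and leukocytes. Some genes are on more than 1 list. Lists with at least 5 tested members, 21 in all, were compared with all other tested genes by limma's camera with the preset correlation between genes of 0.01, and the 168 tests formed 1 Benjamini-Hochberg family. Each test was repeated with the correlation estimated from the data and with fry, which asks whether a list's genes move, on balance, one way.

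Genes were named by a rule. It took RB1, E2F7 and HRAS, and in each comparison the 8 called genes with the largest rise and the 8 with the largest fall (5 each way for the interaction). Those had groups that did not overlap, a mean of at least log2 6 in the brighter group and no provisional name. The largest rises and falls given below are the largest among genes that met these conditions. It also took up to 4 called members of each list with the smallest adjusted p, or, where fewer than 2 were called, the 2 members with the largest change. The text names a selection of the list members. The lists, the comparisons, the tests, the naming rule and the alternatives below were chosen before the data were examined, except where the text says otherwise. The tests of explanations in the closing sections were not part of that plan.

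The alternatives were a fit of only the groups compared, the replicate number as a block, no filter or a filter at log2 6, the mean of all probe sets or the probe set with the largest interquartile range per gene, leaving out probe sets marked as matching several transcripts, testing every probe set, quantile normalization, a shift of each array to the same median, an intensity trend with robust eBayes, array weights, a fold threshold of 2 and leaving out each array in turn, where the lone array of a group was assumed to vary like the other groups. For lists other than replication and mitosis, only the estimated correlation had been planned. For those of them that were called, the further alternatives were added after seeing the data.

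The procedure was tested on simulated data with 10144 genes and 5 simulations per comparison. For shLuc against growing it recovered 58.8% of genes changed by log2 1 and 100% of those changed by log2 2. For the interaction it recovered 14% and 93.2%. In the simulated interaction 5.5% of calls were false. The false share was 4.5% in shLuc against growing, 6.3% in shE2F7 against shLuc and 6% in shRB-E2F7 against shRB. Every simulated group had the same spread per gene. In the data the replicate differences had an SD of 0.218 in shLuc and 0.4795 in growing, so the effect of unequal spread was not tested. With camera, 10 of 10 shifted lists were recovered, and 6 of 190 unshifted lists had an unadjusted p under 0.05. The simulated genes were drawn independently, so this does not test camera on lists of correlated genes. Because comparisons that share a group are correlated without any effect, correlations between comparisons were set against 100 simulations without effects. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.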

Results

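The data were GCRMA log2 expression values from 10 arrays of IMR90 human lung fibroblasts, 2 arrays in each of 5 groups. One group was growing and untreated. The other 4 carried Ras, an oncogene that drives normal fibroblasts into lasting arrest (senescence), with a hairpin against luciferase as a control (shLuc), against RB, a repressor of E2F target genes (shRB), against E2F7, an E2F family member that represses (shE2F7), or against both (shRB-E2F7). The median of the tested genes lay between log2 6.67 and 6.73 in every array. The 2 arrays of a group correlated across genes at r = 0.980 for growing, 0.996 for shLuc, 0.985 for shRB, 0.990 for shE2F7 and 0.985 for shRB-E2F7. On the first principal component (51.6% of the variance) the growing arrays stood apart from the 8 Ras arrays, and on the second (24.8%) the 4 arrays with an RB hairpin stood apart from the other 6. The number of arrays limits the precision. Growing cells received no vector and no drug selection per the labels, so each comparison with them joins the effects of Ras, the hairpin vector and selection.

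RB1 and E2F7 were each lower with their hairpin. RB1 had a mean of log2 9.44 ± 0.04 (SD, n = 2) in shLuc, 6.72 ± 0.19 in shRB, 8.998 ± 0.13 in shE2F7 and 5.72 ± 0.31 in shRB-E2F7. It fell by 2.72 ± 0.24 (SE) in shRB against shLuc (limma adjusted p = 2.32e-05). A second, dimmer probe set of RB1 changed by -0.26 ± 0.30 there (limma unadjusted p = 0.396). E2F7 had a mean of 8.34 ± 0.31 in growing cells, 9.88 ± 0.20 in shLuc, 10.34 ± 0.32 in shRB, 8.71 ± 0.11 in shE2F7 and 9.11 ± 0.08 in shRB-E2F7. Its difference in shE2F7 against shLuc was -1.17 ± 0.23 and did not pass over all genes (limma adjusted p = 0.101, unadjusted p = 0.00028), and the other E2F7 probe set read -1.10 ± 0.31 in a fit of every probe set. With the RB hairpin present the E2F7 hairpin went with a fall of E2F7 (-1.23 ± 0.23, limma adjusted p = 0.0135). HRAS, 1 of the Ras genes, rose by 1.20 ± 0.39 in shLuc against growing (limma adjusted p = 0.0294). That HRAS call was lost without growing replicate 2 (adjusted p = 0.224), shLuc replicate 1 (0.105) or shLuc replicate 2 (0.113). The E2F7 call against shRB was lost without shRB replicate 2 (adjusted p = 0.121) or shRB-E2F7 replicate 2 (0.0864).

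**Figure D1:**
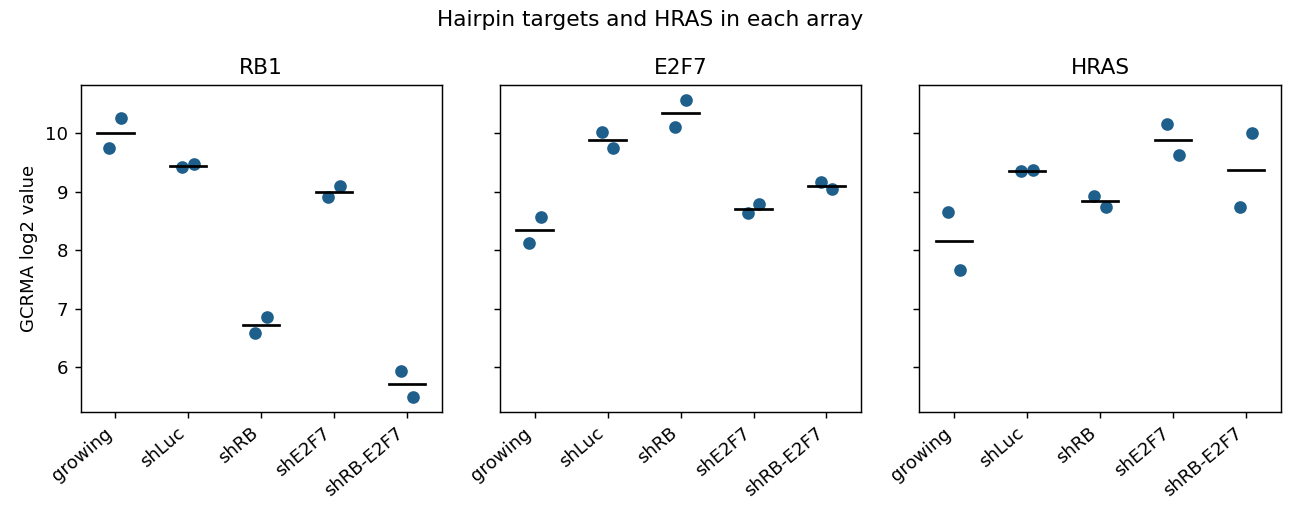
GCRMA log2 values (y axis) of RB1, E2F7 and HRAS in each of the 5 groups (x axis); points are arrays (n = 2 per group) and lines are group means. RB1 had a mean of 6.72 in shRB and 5.72 in shRB-E2F7 against 9.44 in shLuc, and E2F7 a mean of 8.71 in shE2F7 and 9.11 in shRB-E2F7 against 9.88 in shLuc.

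The comparison of shLuc with growing cells asks what Ras cells with the control hairpin express. The largest rises were in the cytokine genes IL1B (9.47 ± 0.57, n = 2 per group) and IL1A (8.31 ± 0.38), and in the chemokine genes CCL20 (9.23 ± 0.46), CXCL5 (8.36 ± 0.71), CXCL1 (8.27 ± 0.37) and CXCL3 (7.63 ± 0.43). TNFSF15, a TNF family cytokine (7.98 ± 0.37), and EHF, an epithelial transcription factor (7.95 ± 0.32), were also among them. All 8 had means below log2 4 in growing cells, so the sizes of their changes are uncertain. The largest falls were in PTN, a secreted growth factor (-6.20 ± 0.25), COL15A1 (-5.94 ± 0.27), FGL2 (-5.86 ± 0.66), the oxytocin receptor gene OXTR (-5.48 ± 0.29), MATN2 (-5.48 ± 0.25), NREP (-5.20 ± 0.22), DLGAP5, a spindle protein gene (-5.01 ± 0.22), and MEST (-4.93 ± 0.25). Limma called 3644 of 10144 genes, 1782 higher and 1862 lower, and 2106 of them changed at least 2-fold. Without shLuc replicate 1 the count was 2182, and without shLuc replicate 2 it was 2218.

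Cell division genes fell in shLuc. Of the 62 mitosis genes tested 60 fell, 0 rose and 2 were not called (60 adjusted over the list alone), with a median of -3.64 (camera adjusted p = 2.07e-43). They included the topoisomerase gene TOP2A (-4.79 ± 0.20), the spindle genes NUSAP1 (-4.71 ± 0.19) and NDC80 (-4.46 ± 0.19), and CEP55, which acts in cytokinesis (-4.76 ± 0.20). Of the 49 replication genes 43 fell, 1 rose and 5 were not called (44 and 1 adjusted over the list alone), with a median of -2.10 (camera adjusted p = 1.29e-22). Examples were GINS2 of the replicative helicase (-3.58 ± 0.20), thymidylate synthase TYMS (-3.32 ± 0.19), CDCA7 (-3.57 ± 0.21) and the polymerase subunit POLE2 (-3.18 ± 0.20). Of 27 recombination and repair genes 22 fell, 0 rose and 5 were not called (22 adjusted over the list alone), among them BRIP1 (-3.67 ± 0.21) and RAD51AP1 (-3.37 ± 0.20). That list had a camera adjusted p of 1.35e-12, and an adjusted p = 0.0908 with an estimated correlation. Of 26 senescence-associated chromatin and nuclear envelope genes 18 fell, 1 rose and 7 were not called (21 and 1 adjusted over the list alone; camera adjusted p = 2.56e-08), including lamin B1, LMNB1 (-4.15 ± 0.23), HMGB2 (-3.61 ± 0.20) and EZH2, which methylates histone H3 (-2.19 ± 0.20). In the E2F and RB families 2 of 15 rose and 5 fell (the same counts adjusted over the list alone; camera adjusted p = 0.5): E2F7 rose (1.55 ± 0.23), while RBL1 (-2.60 ± 0.24) and E2F8 (-1.96 ± 0.20) fell. Of the 9 replication-dependent histone genes 7 rose and 2 were not called (8 adjusted over the list alone), among them H2BC4 (3.39 ± 0.21) and H4C8 (3.49 ± 0.32), with a camera adjusted p of 2.37e-05 and an adjusted p = 0.217 with an estimated correlation. Their median was 1.53, and 1.00 without the filter.

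Of 30 SASP genes, for cytokines and chemokines that senescent cells secrete, 20 rose in shLuc, 4 fell and 6 were not called (20 and 4 adjusted over the list alone), with a median of 3.60, and IL6 rose by 5.94 ± 0.27. Camera gave an adjusted p of 1.04e-08, and an adjusted p = 0.182 with an estimated correlation. Of 19 matrix proteases and inhibitors 12 rose and 3 fell (14 and 4 adjusted over the list alone), with MMP12 (5.40 ± 0.19) and the collagenase MMP1 (3.08 ± 0.23) among those that rose (camera adjusted p = 0.00111, and adjusted p = 0.0907 with an estimated correlation). Of 28 p53 targets 10 rose, 0 fell and 18 were not called (10 adjusted over the list alone), including the stress cytokine GDF15 (5.34 ± 0.43) and the CDK inhibitor gene CDKN1A (2.03 ± 0.21), with a camera adjusted p of 0.000673 and an adjusted p = 0.112 with an estimated correlation. Their median was 0.39, and 0.62 without probe sets marked as matching several transcripts. All 5 genes of the CDK inhibitor list were called, 3 higher and 2 lower (the same counts adjusted over the list alone). CDKN2B rose (3.41 ± 0.24), while CDKN1B (-2.00 ± 0.27) and CDKN3, a phosphatase gene that peaks in dividing cells (-4.76 ± 0.25), fell. The median of that list was 1.22 and its mean -0.02 (camera adjusted p = 0.702). Of 28 RAS-ERK targets and feedback genes 17 rose, 1 fell and 10 were not called (17 and 1 adjusted over the list alone), among them the phosphatase genes DUSP4 (7.19 ± 0.21) and DUSP6 (2.11 ± 0.21) and SPRY2 (2.12 ± 0.20), with a camera adjusted p of 1.9e-05 and an adjusted p = 0.216 with an estimated correlation. Of 15 cholesterol biosynthesis genes 8 rose and 1 fell (10 and 2 adjusted over the list alone), including IDI1 (1.72 ± 0.22), with a camera adjusted p of 0.00749 and an adjusted p = 0.112 with an estimated correlation.

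Matrix genes fell in shLuc. Of 33 collagen and fibrillar matrix genes 25 fell, 0 rose and 8 were not called (28 adjusted over the list alone), with a median of -1.39, including COL3A1 (-4.55 ± 0.23) and decorin, DCN (-3.84 ± 0.30). Camera gave an adjusted p of 7.85e-12, and an adjusted p = 0.111 with an estimated correlation. With the probe set of the largest interquartile range their median was -2.15. Of 21 myofibroblast and TGF-beta targets 11 fell and 3 rose (12 and 3 adjusted over the list alone), with the contractile genes ACTG2 (-3.27 ± 0.23) and TAGLN (-2.82 ± 0.27) among those that fell (camera adjusted p = 0.00509, and adjusted p = 0.3 with an estimated correlation). Their median was -0.57, and -0.92 without probe sets marked as matching several transcripts. The remaining lists were not called by camera. Of 31 interferon-stimulated genes 13 fell and 3 rose (14 and 3 adjusted over the list alone; camera adjusted p = 0.0991): GBP1 fell (-2.80 ± 0.25) and the chemokine gene CXCL10 rose (3.01 ± 0.32). Of 26 lysosome genes 9 rose and 3 fell (camera adjusted p = 0.12), with MCOLN1 up (1.60 ± 0.22). Of 22 genes of the unfolded protein response 2 rose and 7 fell (camera adjusted p = 0.0991), with ASNS down (-2.34 ± 0.22). Of 20 glycolysis genes 2 rose and 4 fell (camera adjusted p = 0.884), with HK2 up (2.43 ± 0.33) and PDK1 down (-2.10 ± 0.24). These 3 lists had the same counts adjusted over the list alone. Of 6 IGF-binding protein genes 2 fell (2 adjusted over the list alone; camera adjusted p = 0.398), IGFBP3 (-2.29 ± 0.27) and IGFBP6 (-1.37 ± 0.29). Of 10 pro-apoptotic targets 4 rose and 1 fell (the same counts adjusted over the list alone; camera adjusted p = 0.351). Of 29 ribosomal protein genes limma called 0 (0 adjusted over the list alone), with camera at an adjusted p of 0.493 and fry at 0.667.

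Markers of other cell types were few. The 1 epithelial marker tested, KRT18, differed by 0.12 ± 0.24 between shLuc and growing (limma adjusted p = 0.738). All 4 endothelial markers tested were called, ROBO4 (3.62 ± 0.23), CLDN5 (1.25 ± 0.23) and PECAM1 (0.74 ± 0.23) higher and TEK (-2.21 ± 0.23; 0.10 on its other probe set) lower, so the 4 did not move together. The PECAM1 call was lost without growing replicate 2 (adjusted p = 0.121), shLuc replicate 1 (0.169) or shLuc replicate 2 (0.0677). No leukocyte marker passed the expression filter.

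The comparison of shRB with shLuc asks what RB holds down in Ras cells. Replication genes rose: CCNE2, a cyclin of S-phase entry, by 4.25 ± 0.19 (n = 2 per group), the helicase gene MCM3 by 2.79 ± 0.20, and CDC6 and CDC7, which act at replication origins, by 2.79 ± 0.20 and 2.76 ± 0.20. Other large rises were in the chemokine gene CXCL6 (3.71 ± 0.34), RGS5 (3.59 ± 0.50), DTL, which acts in licensing control (3.08 ± 0.24), CDCA7 (3.06 ± 0.21), SPIN4 (3.06 ± 0.25), TMEM106C (3.01 ± 0.21) and the PCNA-binding gene PCLAF (2.88 ± 0.21). The largest falls besides RB1 were in CES1, a carboxylesterase gene (-2.76 ± 0.20), the cornified envelope genes CRCT1 (-2.62 ± 0.23) and LCE3D (-2.20 ± 0.29), the cyclin gene CCND2 (-2.46 ± 0.29), SLC35F3 (-2.30 ± 0.26), the neurofilament gene NEFL (-2.07 ± 0.24) and DUSP4 (-1.91 ± 0.21). Limma called 2334 genes, 1206 higher and 1128 lower, and 1028 of them changed at least 2-fold. The count was 728 without shLuc replicate 1, 610 without shLuc replicate 2 and 1183 without shRB replicate 2.

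Of the 49 replication genes 42 rose with the RB hairpin, 0 fell and 7 were not called (43 adjusted over the list alone), with a median of 1.71 (camera adjusted p = 1.01e-32). The median level of the list in the arrays was -0.38 ± 0.18 (SD, n = 2) in shRB relative to growing, against -2.08 ± 0.08 in shLuc. Of the 62 mitosis genes 26 rose, 0 fell and 36 were not called (31 adjusted over the list alone), with a median of 0.57, including NUSAP1 (1.76 ± 0.19), SMC2 of condensin (1.70 ± 0.20) and CDK1, the kinase of mitotic entry (1.85 ± 0.22). Camera gave the mitosis list an adjusted p of 1.66e-12, and an adjusted p = 0.105 with an estimated correlation. Its median level was -2.82 ± 0.06 in shRB and -3.65 ± 0.05 in shLuc. Of 27 recombination and repair genes 18 rose and 0 fell (19 adjusted over the list alone), among them BARD1 and BRIP1 (1.99 ± 0.20 and 1.99 ± 0.21), with a camera adjusted p of 5.71e-11 and an adjusted p = 0.105 with an estimated correlation. The repair median was 0.82, and 1.28 with the filter at log2 6. Of 26 chromatin and nuclear envelope genes 14 rose and 2 fell (16 and 2 adjusted over the list alone; camera adjusted p = 3.96e-07), including HELLS (2.83 ± 0.21), EZH2 (2.51 ± 0.20) and LMNB1 (2.39 ± 0.23). In the E2F and RB families 5 of 15 rose and 4 fell (the same counts adjusted over the list alone; camera adjusted p = 0.551), with the pocket protein genes RBL1 (1.99 ± 0.24) and RBL2 (1.32 ± 0.27; 0.41 on its second probe set) higher. The RBL2 call was lost without shLuc replicate 2 (adjusted p = 0.0818).

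Secretory and interferon-stimulated genes also rose with the RB hairpin. Of 30 SASP genes 16 rose, 0 fell and 14 were not called (18 adjusted over the list alone), with a median of 1.02, including IL6 (2.10 ± 0.27) and IL11 (1.93 ± 0.30). Camera gave an adjusted p of 3.73e-08, and an adjusted p = 0.2 with an estimated correlation. Of 31 interferon-stimulated genes 17 rose, 1 fell and 13 were not called (22 and 2 adjusted over the list alone), with a median of 0.79, including the antiviral genes IFIT1 (2.33 ± 0.23) and IFIT2 (2.28 ± 0.24) and the chemokine gene CXCL11 (2.29 ± 0.24). That list had a camera adjusted p of 4.32e-10, and an adjusted p = 0.217 with an estimated correlation. Of 33 collagen and matrix genes 6 rose and 0 fell (6 adjusted over the list alone; camera adjusted p = 0.0724), including periostin, POSTN (2.21 ± 0.23), and COL15A1 (1.47 ± 0.27). Of 9 histone genes 2 fell and 0 rose (3 adjusted over the list alone; camera adjusted p = 0.306), H2BC4 (-1.49 ± 0.21) and H2AC6 (-1.04 ± 0.27). The H2AC6 call was lost without shLuc replicate 1 (adjusted p = 0.108), shLuc replicate 2 (0.0931) or shRB replicate 2 (0.13). Of 20 glycolysis genes 4 rose and 3 fell (the same counts adjusted over the list alone; camera adjusted p = 0.525), with the enolase gene ENO2 higher (1.89 ± 0.23). The epithelial marker KRT18 fell (-1.38 ± 0.24, limma adjusted p = 0.00236), as did the endothelial marker ROBO4 (-1.32 ± 0.23), while CLDN5 (1.49 ± 0.23) and TEK (0.97 ± 0.23) rose. The TEK call was lost without shLuc replicate 1 (adjusted p = 0.0797), shLuc replicate 2 (0.09) or shRB replicate 2 (0.0838). No other list was called by camera in this comparison.

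The comparison of shE2F7 with shLuc asks what the E2F7 hairpin changes while RB is present. POSTN, a matrix protein gene (1.73 ± 0.23, n = 2 per group), CHN1 (1.497 ± 0.20) and AMIGO2 (1.44 ± 0.22) rose. The cytokine gene IL24 (-2.37 ± 0.32), the prostaglandin synthase gene PTGS2 (-2.19 ± 0.24), CES1 (-2.02 ± 0.20), DNER (-1.90 ± 0.22), the hyaluronan-degrading CEMIP (-1.86 ± 0.30), thrombomodulin, THBD (-1.45 ± 0.19), the phospholipase gene PLA2G4A (-1.43 ± 0.22) and MMP12 (-1.32 ± 0.19) fell. Limma called 14 genes, 5 higher and 9 lower, against 594 at an unadjusted p under 0.05. The count was 224 with array weights, 23 with a fit of only the groups compared and 22 with an intensity trend, but 4 without shLuc replicate 1, 1 without shLuc replicate 2 and 4 without shE2F7 replicate 1. Of the genes named, CES1 was called with any array left out, and the other calls were each lost without at least 1 array, with adjusted p values up to 0.464.

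Replication and mitosis genes shifted upward as lists by small amounts in shE2F7, with no member called over all genes. Of 62 mitosis genes limma called 0 over all genes and 14 adjusted over the list alone, all higher, with a median of 0.42. HMMR, a spindle protein gene, differed by 0.90 ± 0.22 (limma adjusted p = 0.178). Its means of 3.00 in shLuc and 3.90 in shE2F7 lay below log2 4, so the size of its change is uncertain. Camera gave the mitosis list an adjusted p of 4.9e-22, and an adjusted p = 0.0619 with an estimated correlation. Of 49 replication genes limma called 0 over all genes and 9 adjusted over the list alone, all higher, with a median of 0.26 (camera adjusted p = 1.35e-12; median 0.42 with the filter at log2 6), and CDCA7 differed by 1.05 ± 0.21 (limma adjusted p = 0.101). Collagen and matrix genes had a median of 0.41 with 1 of 33 called, POSTN (7 adjusted over the list alone), and a camera adjusted p of 7.62e-09, with an adjusted p = 0.166 with an estimated correlation and a fry adjusted p of 0.0699. Myofibroblast genes had a median of 0.37 with 0 of 21 called by limma (4 adjusted over the list alone), a camera adjusted p of 8.21e-08 and an adjusted p = 0.09 with an estimated correlation, with TAGLN at 1.52 ± 0.27 and ACTG2 at 1.28 ± 0.23 (limma adjusted p = 0.0612 for each). Chromatin genes had a median of 0.18 with 0 of 26 called by limma (0 adjusted over the list alone), a camera adjusted p of 0.00103 and an adjusted p = 0.0797 with an estimated correlation. The p53 targets had a median of -0.17 with 0 of 28 called by limma (1 lower adjusted over the list alone), a camera adjusted p of 0.00186 and an adjusted p = 0.144 with an estimated correlation. Of 22 other settings 3 lost this call, with an adjusted p of up to 0.0992, and the median was -0.13 without shLuc replicate 1 (0.0632) and -0.27 without shLuc replicate 2, where the call was kept. SASP genes had a median of -0.19 and interferon-stimulated genes a median of 0.10, each with 0 called by limma over all genes and over the list alone (camera adjusted p = 0.116 and 0.194).

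The comparison of shRB-E2F7 with shLuc asks what both hairpins change together. The largest rises were in the interferon-stimulated genes IFIT1 (4.57 ± 0.23, n = 2 per group), IFI6 (4.43 ± 0.32), CXCL10 (4.09 ± 0.32) and IFI44 (4.09 ± 0.24). Next came CCNE2 (4.01 ± 0.19), PTN (3.55 ± 0.25), CMPK2, an interferon-induced nucleotide kinase gene (3.51 ± 0.25), and CDCA7 (3.42 ± 0.21). The largest falls besides RB1 were in the cornified envelope genes LCE3D (-4.37 ± 0.29), IVL (-3.37 ± 0.21) and CRCT1 (-2.49 ± 0.23), and in NEFL (-3.18 ± 0.24), the nuclear receptor gene NR4A2 (-2.81 ± 0.42), CES1 (-2.78 ± 0.20) and CCND2 (-2.77 ± 0.29). Limma called 2644 genes, 1365 higher and 1279 lower, and 1210 of them changed at least 2-fold. The count was 1016 without shLuc replicate 1, 954 without shLuc replicate 2 and 1362 without shRB-E2F7 replicate 1. Of these genes 752 also rose and 593 also fell in shRB against shLuc, where 162.3 and 142.2 would be shared by independent calls. The calls are not independent, since both comparisons use the same shLuc arrays and both groups carry the RB hairpin. No overlap without effects was simulated. The changes in the 2 comparisons, a pair not planned beforehand, correlated across genes at r = 0.746, against 0.499 in simulations without effects. There the shared shLuc arrays alone give a correlation. That simulated r holds noise alone, so it is no yardstick once groups differ. The covariance was 0.3397, against 0.0318 in the simulations. For shRB and shE2F7, each against shLuc, r was 0.209 against 0.5, and the covariance 0.0397 against 0.0318. Genes are not independent replicates.

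Of the 49 replication genes 45 rose and 0 fell (46 adjusted over the list alone), with a median of 1.82 (camera adjusted p = 2.97e-33), including the primase gene PRIM1 (3.50 ± 0.19) and MCM3 (2.94 ± 0.20). Of the 62 mitosis genes 54 rose and 0 fell (59 adjusted over the list alone), with a median of 1.66 (camera adjusted p = 8.17e-35), including NUSAP1 (2.89 ± 0.19), NDC80 (2.56 ± 0.19) and CDK1 (2.58 ± 0.22). Of 27 recombination and repair genes 21 rose and 0 fell (24 adjusted over the list alone), including RAD51AP1 (2.06 ± 0.20), with a camera adjusted p of 2.44e-13 and an adjusted p = 0.09 with an estimated correlation. Of 26 chromatin genes 15 rose and 2 fell (18 and 3 adjusted over the list alone; camera adjusted p = 7.18e-08), including EZH2 (2.82 ± 0.20) and LMNB1 (2.61 ± 0.23). Of 31 interferon-stimulated genes 29 rose, 1 fell and 1 was not called (29 and 1 adjusted over the list alone), with a median of 2.35, including MX1 (3.13 ± 0.22) and OASL (2.78 ± 0.19). Camera gave that list an adjusted p of 1.73e-27, and an adjusted p = 0.0797 with an estimated correlation. Of 30 SASP genes 13 rose and 2 fell (15 and 2 adjusted over the list alone), with CXCL6 (3.34 ± 0.34) and CCL2 (2.49 ± 0.36) among those that rose, a camera adjusted p of 0.00114, a fry adjusted p of 0.0574 and an adjusted p = 0.469 with an estimated correlation. The SASP median was 0.63, 0.37 with the filter at log2 6 and 0.95 with the probe set of the largest interquartile range. Of 33 collagen and matrix genes 7 rose and 0 fell (7 adjusted over the list alone), including POSTN (2.72 ± 0.23) and COL15A1 (1.88 ± 0.27), with a camera adjusted p of 0.0441 and an adjusted p = 0.654 with an estimated correlation. Of 22 other settings 6 lost this call, among them leaving out shLuc replicate 1 (median 0.09, adjusted p = 0.0652) and shRB-E2F7 replicate 2 (0.15, 0.102, the highest of the 6). The matrix median was 0.25, and it was 0.16 with the filter at log2 6, where the call was lost (0.0991). It was 0.41 with the probe set of the largest interquartile range and 0.40 without shRB-E2F7 replicate 1. Of 22 unfolded protein response genes 4 rose and 0 fell (4 adjusted over the list alone), including ASNS (2.09 ± 0.22), with a camera adjusted p of 0.0481 and an adjusted p = 0.392 with an estimated correlation. Of 22 other settings 8 lost this call, among them leaving out any 1 of the 4 arrays compared, with the highest adjusted p without probe sets marked as matching several transcripts (median 0.21, adjusted p = 0.318). With the probe set of the largest interquartile range the median was 0.44 (adjusted p = 0.0596). KRT18 differed by -0.57 ± 0.24 (limma adjusted p = 0.1), ROBO4 fell (-1.49 ± 0.23) and TEK rose (0.86 ± 0.23; -0.16 on its other probe set). The TEK call was lost with the mean of its probe sets (0.35, adjusted p = 0.203) and without any 1 of 3 of the 4 arrays compared.

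**Figure D2:**
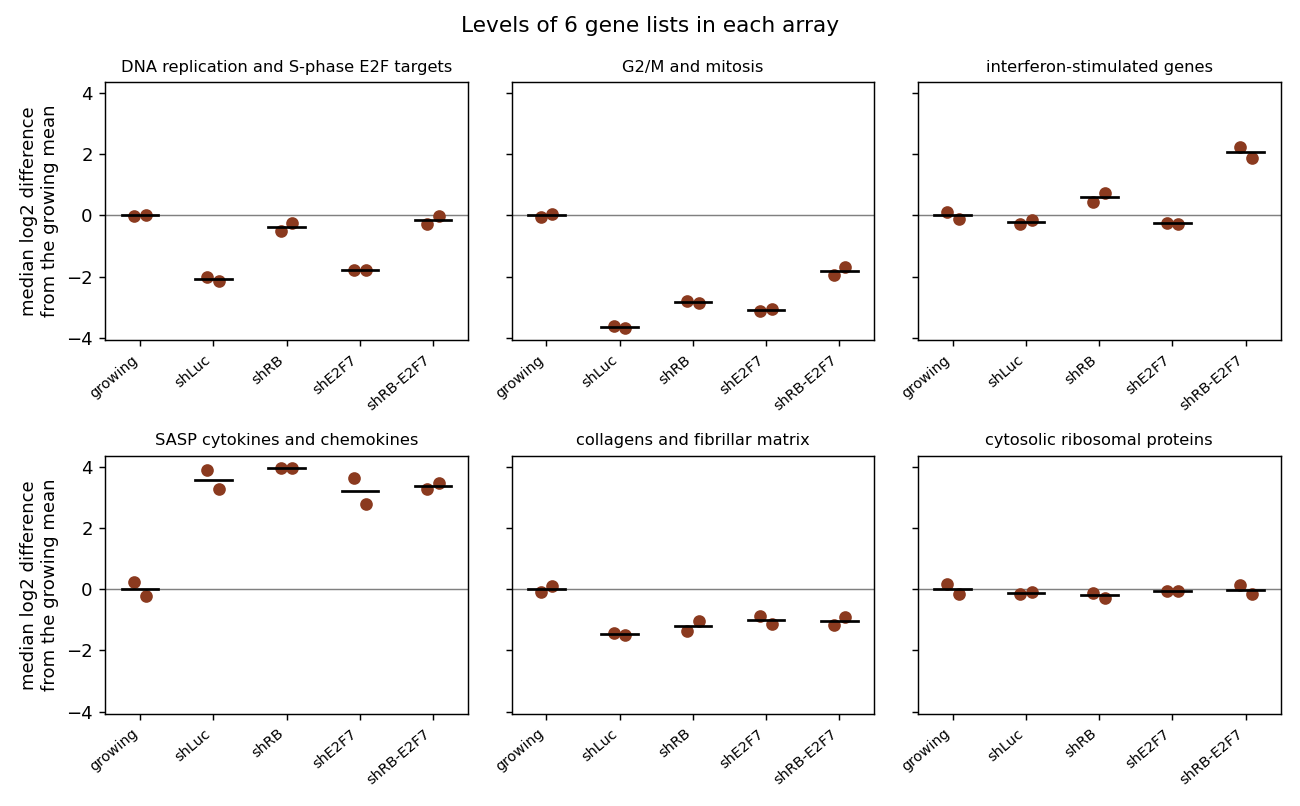
Median log2 difference of the members of 6 gene lists from the growing mean (y axis) in each of the 5 groups (x axis); points are arrays (n = 2 per group) and lines are group means. Replication genes were at -2.08 in shLuc and -0.15 in shRB-E2F7, mitosis genes at -3.65 and -1.80, and interferon-stimulated genes at -0.20 and 2.06.

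The comparison of shRB-E2F7 with shRB asks what the E2F7 hairpin adds once RB is low. Mitosis genes rose with it: NDC80 by 1.75 ± 0.19 (n = 2 per group), the cyclin genes CCNB2 and CCNB1 by 1.79 ± 0.22 and 1.67 ± 0.22, and survivin, BIRC5, by 1.56 ± 0.20. Interferon-stimulated genes rose too, with IFI27 (2.68 ± 0.29), IFI44 (2.49 ± 0.24), IFITM1 (2.45 ± 0.34), MX1 (2.43 ± 0.22), IFI6 (2.37 ± 0.32), IFIT1 (2.24 ± 0.23) and the interferon-response transcription factor gene IRF9 (1.88 ± 0.21). The other largest rises were in CST1 (2.82 ± 0.63), SLC14A1 (2.37 ± 0.42) and COL3A1 (2.04 ± 0.23). The largest falls were in PDK4, a kinase gene of glucose oxidation (-3.26 ± 0.46), LCE3D (-2.18 ± 0.29), the pocket protein gene RBL2 (-2.03 ± 0.27), IVL (-1.99 ± 0.21), TSPAN12 (-1.86 ± 0.21), the chemokine gene PPBP (-1.80 ± 0.32), LCE2B (-1.78 ± 0.28) and SERPINB4 (-1.65 ± 0.35). ADAMTS5, a matrix protease gene with means below log2 6 in both groups, changed by -2.38 ± 0.26 (limma adjusted p = 0.00101). RB1 also fell further (-1.005 ± 0.24, limma adjusted p = 0.0314). Limma called 550 genes, 304 higher and 246 lower, and 330 of them changed at least 2-fold. The count was 260 with array weights, 307 with a fit of only the groups compared, 877 without growing replicate 1 or 2, 259 without shLuc replicate 1 or 2, 98 without shRB replicate 2, 253 without shRB-E2F7 replicate 1 and 129 without shRB-E2F7 replicate 2.

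Of the 62 mitosis genes 38 rose with the E2F7 hairpin added, 0 fell and 24 were not called (51 adjusted over the list alone), with a median of 1.00 (camera adjusted p = 2.66e-29). Of the 49 replication genes 2 rose, 0 fell and 47 were not called (2 adjusted over the list alone), POLE2 (0.98 ± 0.20) and GINS4 (1.44 ± 0.33), with a median of 0.16. That replication list had a camera adjusted p of 0.0227, and an adjusted p = 0.328 with an estimated correlation. It was not called without shRB replicate 1 (adjusted p = 0.131, median 0.16) or shRB-E2F7 replicate 2 (0.0915, median 0.14), and the median was 0.27 without shRB replicate 2, 0.26 without shRB-E2F7 replicate 1 and 0.31 with the probe set of the largest interquartile range. Of 31 interferon-stimulated genes 25 rose, 0 fell and 6 were not called (30 adjusted over the list alone), with a median of 1.39, a camera adjusted p of 1.18e-28 and an adjusted p = 0.0779 with an estimated correlation. Of 30 SASP genes 2 fell and 0 rose (2 adjusted over the list alone), FGF2 (-1.59 ± 0.26) and TNFAIP3 (-1.23 ± 0.24), with a median of -0.34, a camera adjusted p of 0.0172 and an adjusted p = 0.613 with an estimated correlation. The SASP list was not called with fry (adjusted p = 0.381), without shRB replicate 1 (0.16, median -0.35) or without shRB-E2F7 replicate 2 (0.115, median -0.21), and its median was -0.20 with the mean of all probe sets, each tried after seeing the data. In the E2F and RB families 2 of 15 rose and 3 fell (the same counts adjusted over the list alone), with E2F8 higher (1.08 ± 0.20).

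Several gene calls of shRB-E2F7 against shRB were lost with a single array left out. Those of CST1, SLC14A1, PPBP, SERPINB4, RB1, POLE2, GINS4, FGF2, TNFAIP3, E2F8 and the endothelial marker CLDN5 were each lost without at least 1 of the 4 arrays compared, with the highest adjusted p at 0.138, 0.0906, 0.0907, 0.156, 0.201, 0.0811, 0.223, 0.0606, 0.102, 0.0701 and 0.0856 in that order. CLDN5 fell by 1.29 ± 0.23, and KRT18 differed by 0.81 ± 0.24 (limma adjusted p = 0.0715). COL3A1 was not called when probe sets marked as matching several transcripts were left out (0.06, adjusted p = 0.902), nor TSPAN12 with the mean of its probe sets (-0.65, adjusted p = 0.083). The second probe set of RBL2 differed by -0.16, and the mean of both by -1.09 (adjusted p = 0.0247).

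**Figure D3:**
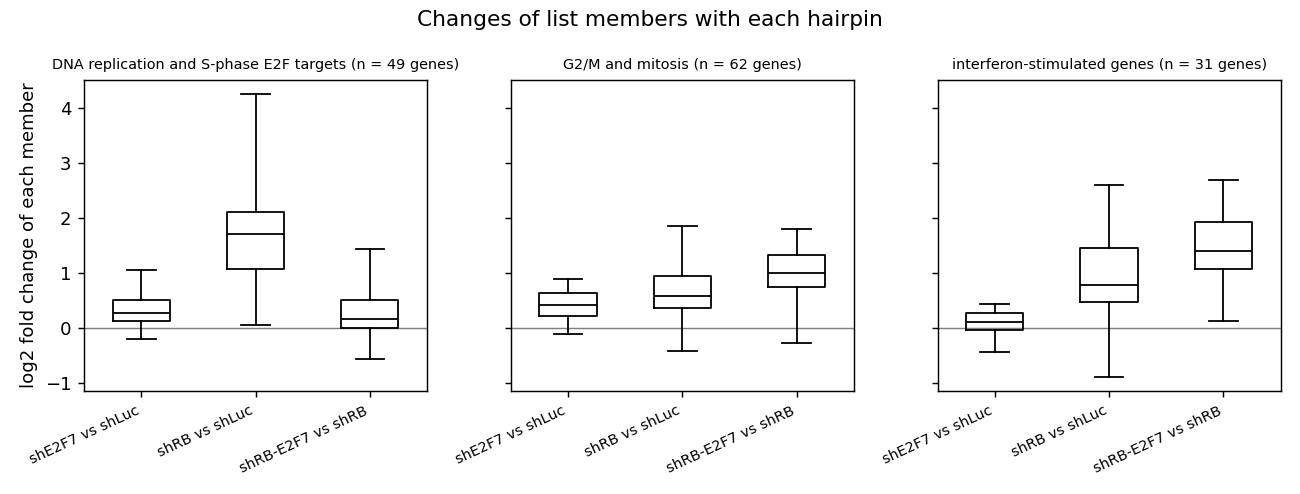
Log2 fold change of each list member (y axis) with the E2F7 hairpin alone, the RB hairpin alone and the E2F7 hairpin added to the RB hairpin (x axis); boxes show the median and quartiles and whiskers the full range over 49 replication, 62 mitosis and 31 interferon-stimulated genes. The medians for the added E2F7 hairpin were 0.16, 1.00 and 1.39.

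The comparison of shRB-E2F7 with shE2F7 asks what the RB hairpin changes once E2F7 is lower. CXCL10 (4.53 ± 0.32, n = 2 per group), IFIT1 (4.50 ± 0.23), IFI6 (4.10 ± 0.32), IFI44 (3.94 ± 0.24) and CMPK2 (3.79 ± 0.25) rose most, followed by CCNE2 (3.29 ± 0.19), CXCL6 (3.10 ± 0.34) and TMEM106C (3.04 ± 0.21). Besides RB1, LCE3D (-3.13 ± 0.29), CCND2 (-2.75 ± 0.29), HINT3 (-2.36 ± 0.39), IVL (-2.20 ± 0.21), SIDT2 (-2.19 ± 0.30), LCE2B (-2.06 ± 0.28) and NEFL (-2.03 ± 0.24) fell most. Of 49 replication genes 41 rose and 0 fell (46 adjusted over the list alone; median 1.60, camera adjusted p = 6.46e-30). Of 62 mitosis genes 53 rose and 0 fell (57 adjusted over the list alone; median 1.25, camera adjusted p = 1.81e-28). Of 31 interferon-stimulated genes 29 rose and 0 fell (29 and 1 adjusted over the list alone), with a median of 2.33, a camera adjusted p of 6.75e-29 and an adjusted p = 0.0779 with an estimated correlation. Of 26 lysosome genes 8 fell and 1 rose (12 and 3 adjusted over the list alone), including MCOLN1 (-1.96 ± 0.22), with a camera adjusted p of 0.0184 and an adjusted p = 0.392 with an estimated correlation. The lysosome list was not called without probe sets marked as matching several transcripts (median -0.27, adjusted p = 0.62), with the probe set of the largest interquartile range (-0.39, 0.0619), without shE2F7 replicate 1 (-0.42, 0.0512) or without shRB-E2F7 replicate 1 (-0.34, 0.0788). Limma called 2339 genes, 1250 higher and 1089 lower, and 1060 of them changed at least 2-fold. The count was 1126 without shE2F7 replicate 1, 967 without shE2F7 replicate 2 and 966 without shRB-E2F7 replicate 1.

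In the same comparison 18 of 27 recombination and repair genes rose and 0 fell (22 adjusted over the list alone), including FANCL (2.14 ± 0.22), with a camera adjusted p of 1.17e-12 and an adjusted p = 0.0908 with an estimated correlation. Of 26 chromatin genes 14 rose and 3 fell (16 and 3 adjusted over the list alone; camera adjusted p = 4.51e-06), including EZH2 (2.47 ± 0.20). Of 30 SASP genes 15 rose and 1 fell (16 and 2 adjusted over the list alone), including IL6 (2.41 ± 0.27) and CSF3 (2.59 ± 0.39), with a camera adjusted p of 3.73e-05 and an adjusted p = 0.336 with an estimated correlation. The endothelial marker ROBO4 fell (-1.87 ± 0.23) and TEK rose (0.92 ± 0.23; -0.29 on its other probe set). This TEK call was lost with the mean of its probe sets (0.32, adjusted p = 0.243) and without any 1 of 3 of the 4 arrays. KRT18 differed by -0.65 ± 0.24 (limma adjusted p = 0.0693).

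The comparison of shRB-E2F7 with growing cells asks how far cells with both hairpins stay from the growing state. Replication genes were near the growing level: of 49, 8 were higher, 6 lower and 35 not called (8 and 7 adjusted over the list alone), with a median of -0.15 (camera adjusted p = 0.76). The cyclin E genes CCNE1 (3.07 ± 0.20, n = 2 per group) and CCNE2 (1.95 ± 0.19) rose and thymidine kinase, TK1, fell (-1.83 ± 0.25). Mitosis genes stayed lower: 55 of 62 fell, 0 rose and 7 were not called (57 and 1 adjusted over the list alone), with a median of -1.78 (camera adjusted p = 1.18e-28), including TOP2A (-2.62 ± 0.20) and KIF20A (-2.39 ± 0.19). The largest rises were in CXCL3 (9.42 ± 0.43), IL1B (9.39 ± 0.57), CXCL1 (9.32 ± 0.37), CCL20 (9.32 ± 0.46), IL1A (9.31 ± 0.38), CXCL2 (9.09 ± 0.51), the survival gene BCL2A1 (8.88 ± 0.39) and CXCL5 (8.47 ± 0.71). The largest falls were in FGL2 (-6.28 ± 0.66), MATN2 (-5.18 ± 0.25), the chemokine gene CXCL12 (-4.91 ± 0.34), OXTR (-4.69 ± 0.29), EFEMP1 (-4.61 ± 0.31), ID4 (-4.46 ± 0.32), TOX (-4.34 ± 0.23) and RB1 (-4.28 ± 0.24). Limma called 2847 genes, 1369 higher and 1478 lower, and 1641 of them changed at least 2-fold. The count was 2137 with a fit of only the groups compared and 1999 with array weights. Without growing replicate 2 the count was 1895.

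Secretory genes stayed high in shRB-E2F7 against growing. Of 30 SASP genes 24 rose and 3 fell (25 and 3 adjusted over the list alone), with a median of 3.28, and IL6 rose by 7.66 ± 0.27. Camera gave an adjusted p of 2.99e-17, and an adjusted p = 0.0886 with an estimated correlation. Among 31 interferon-stimulated genes 28 rose and 1 fell (29 and 1 adjusted over the list alone), with a median of 2.19, a camera adjusted p of 3.98e-20 and an adjusted p = 0.104 with an estimated correlation. Of 33 collagen and matrix genes 20 fell and 1 rose (24 and 1 adjusted over the list alone), including COL15A1 (-4.06 ± 0.27), with a camera adjusted p of 2.74e-09 and an adjusted p = 0.156 with an estimated correlation. Of 28 RAS-ERK genes 14 rose and 2 fell (15 and 2 adjusted over the list alone), including DUSP4 (5.14 ± 0.21), with a camera adjusted p of 8.44e-07 and an adjusted p = 0.167 with an estimated correlation. Of 28 p53 targets 10 rose and 0 fell (11 adjusted over the list alone), including GDF15 (5.22 ± 0.43; 0.75 and adjusted p = 0.152 on its probe set with the largest interquartile range), with a camera adjusted p of 0.00458 and an adjusted p = 0.167 with an estimated correlation. Their median was 0.30, and 0.56 with the filter at log2 6. Of 27 recombination and repair genes 10 fell and 3 rose (11 and 3 adjusted over the list alone), with a camera adjusted p of 0.016 and an adjusted p = 0.566 with an estimated correlation. Of 22 other settings 4 lost the repair call, with the highest adjusted p at the filter of log2 6 (median -0.40, adjusted p = 0.415), and without growing replicate 2 the median was -0.28 (0.0822). Matrix proteases had a median of 0.93 (12 of 19 rose and 3 fell, the same adjusted over the list alone; camera adjusted p = 0.000673, and adjusted p = 0.0886 with an estimated correlation). Histone genes had a median of 1.67 (8 of 9 rose, the same adjusted over the list alone; camera adjusted p = 7.58e-06, and adjusted p = 0.203 with an estimated correlation). Myofibroblast genes had a median of -0.50 (7 of 21 fell and 1 rose, 8 and 1 adjusted over the list alone; camera adjusted p = 0.0145, adjusted p = 0.36 with an estimated correlation, and 0.0585 without probe sets marked as matching several transcripts). Of the 5 CDK inhibitor genes 3 rose and 2 fell (the same counts adjusted over the list alone; camera adjusted p = 0.416), with CDKN2A, which encodes p16, higher (2.24 ± 0.28). The endothelial markers ROBO4 (2.13 ± 0.23), CLDN5 (1.44 ± 0.23) and PECAM1 (1.22 ± 0.23) rose and TEK fell (-1.35 ± 0.23; -0.06 on its other probe set).

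The interaction asks whether the E2F7 hairpin changes a gene by another amount when RB is also low. Interferon-stimulated genes did so: IFI27 (2.73 ± 0.41), IFI44 (2.35 ± 0.35), IFIT1 (2.17 ± 0.32) and IFI44L (2.02 ± 0.30) had a positive interaction, as had COLEC10 (2.47 ± 0.35), KYNU, an enzyme of tryptophan breakdown (2.18 ± 0.35), and CES1 (2.00 ± 0.28). TSPAN12 had a negative one (-2.00 ± 0.30; -0.13 on its other probe set). Of the 31 tested, 6 were called higher and 25 were not called (26 adjusted over the list alone), with a median of 1.45, a camera adjusted p of 5.43e-29 and an adjusted p = 0.0779 with an estimated correlation. Of 62 mitosis genes limma called 0 over all genes and 10 adjusted over the list alone, with a median of 0.54, a camera adjusted p of 4.11e-12 and an adjusted p = 0.105 with an estimated correlation. CCNB2 and AURKB, with the largest interactions of that list, had means of 3.29 and 2.90 in shLuc and 3.58 and 3.04 in shE2F7. CCNB1 stood higher, at 5.85 and 6.21. A change between values below log2 4 is uncertain in size, and whether background raised the mitosis interaction was not tested. Replication genes had a median of -0.09 with 0 of 49 called by limma (0 adjusted over the list alone; camera adjusted p = 0.156, fry adjusted p = 0.229). RBL2 had an interaction of -2.20 ± 0.38 that did not pass (limma adjusted p = 0.0582), and of -0.32 on its second probe set. Collagen genes had a median of -0.23 (camera adjusted p = 0.0159, and adjusted p = 0.599 with an estimated correlation), and myofibroblast genes a median of -0.26 (camera adjusted p = 0.0159, and adjusted p = 0.366 with an estimated correlation), each with 0 members called by limma over all genes. The collagen call was lost with fry (adjusted p = 0.357), without shRB replicate 2 (median -0.01, adjusted p = 0.477) and without shE2F7 replicate 1 (-0.28, 0.0696). Its median was -0.13 without shLuc replicate 1 and -0.58 without shRB replicate 1. Of 22 other settings 5 lost the myofibroblast call, with the highest adjusted p without probe sets marked as matching several transcripts (0.269), and the median was -0.16 with the probe set of the largest interquartile range (adjusted p = 0.193). Limma called 13 genes, 12 higher and 1 lower, against 1219 at an unadjusted p under 0.05. The count was 30 with array weights, 21 with a fit of only the groups compared, 7 with the mean of all probe sets, 6 with the filter at log2 6, 21 without growing replicate 1 or 2, 0 without shLuc replicate 1 or 2, shRB replicate 1, shE2F7 replicate 1 or 2 or shRB-E2F7 replicate 1, 3 without shRB replicate 2 and 2 without shRB-E2F7 replicate 2. KYNU was also lost with the filter at log2 6, with every other choice of probe set tried and with quantile normalization.

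Of the 57 list calls made with the preset correlation, 14 held with an estimated correlation. They were the replication list in shLuc against growing, in shRB, shE2F7 and shRB-E2F7 against shLuc and in shRB-E2F7 against shE2F7, the mitosis list in shLuc against growing and in shRB-E2F7 against each of shLuc, shRB, shE2F7 and growing, and the chromatin list in shLuc against growing, in shRB and shRB-E2F7 against shLuc and in shRB-E2F7 against shE2F7.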

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

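The tests of mitosis against replication genes, of single arrays, of carrying 2 hairpins, of RB1 hybridisation and of the E2F7 hairpin alone were chosen only after the result was seen. Those of background values, dimmer probe sets, room to rise and growing-like cells were also framed around patterns seen in these data. Their bounds were therefore set with the patterns known. A difference between groups, here an effect of the E2F7 hairpin that differed with and without the RB hairpin, singled out 13 genes and 4 lists. The genes named had interactions of 2.47 (COLEC10), 2.35 (IFI44), 2.18 (KYNU), 2.17 (IFIT1), 2.00 (CES1) and -2.00 (TSPAN12; -0.13 on its other probe set) on the log2 scale. The list medians were 1.45 for interferon-stimulated genes, 0.54 for mitosis, -0.23 for collagens and -0.26 for myofibroblast genes. Each of these list calls was lost with an estimated correlation. CES1 was lower than in shLuc in all 3 other Ras groups, by 2.76 in shRB, 2.02 in shE2F7 and 2.78 in shRB-E2F7, so its interaction is a second fall that did not add to the first. Its means were 4.90 in shRB and 4.89 in shRB-E2F7. A further fall of the size seen in shE2F7 would have ended below log2 4, so a limit set by background stays open.

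Interferon-stimulated genes had a median interaction of 1.45, above 0 in 31 of 31 members, though limma called 6 of them, and 0 genes in all without any 1 of 6 arrays. A single array does not account for the shift of the list, since the lower array with both hairpins had a list median 1.14 above the highest of the other 6 Ras arrays. Values near background do not account for it either, since the 8 members above log2 4 in every Ras group had a median interaction of 1.13, all 8 above 0. An effect of carrying 2 hairpins, such as a response to double-stranded RNA, cannot be told apart from lower RB1 and E2F7 together. Only 1 group carried 2 hairpins and no group had 2 control hairpins. Lower RB1 and E2F7 together may raise these genes, and that stays open beside the hairpin load. With both hairpins E2F7 differed by -0.78 from shLuc and by 0.77 from growing cells (limma adjusted p = 0.0288 and 0.0281), so it was lowered but not lost. RB1 was also lower than in shRB (-1.005), which the interaction does not separate from lower E2F7. The arrays do not measure protein.

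With the E2F7 hairpin added to the RB hairpin, mitosis genes rose by a median 0.838 more than replication genes (camera of one list against the other, p = 7.75e-12, and p = 0.00678 with an estimated correlation). Among 21 mitosis and 28 replication members with an shRB mean between log2 5 and 9, the gap was smaller, at 0.630 (95% interval 0.302 to 0.923). This met the bounds set against dimmer mitotic probe sets as the cause, but the lower bound only narrowly. The interval resamples genes as if independent, so dimmer probe sets may still account for part of the gap. Growing-like cells mixed into the cultures do not account for it, since 16 genes high in growing cells stood at a median 8.51% of the growing level, 29.2% of the share of 29.14% that mitosis genes had, which leaves cycling Ras cells open. Replication genes that were already back at the growing level may have had no room to rise. The 19 members still below it in shRB rose by a median of 0.519 (interval 0.221 to 0.647), too near the bounds set to tell. That explanation and a stronger hold of E2F7 on mitosis genes therefore cannot be told apart. RB1 was also lower with both hairpins than with the RB hairpin alone (-1.005, limma adjusted p = 0.0314). The comparison does not separate this further fall of RB1 from the fall of E2F7.

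RBL2, a gene of the RB family, was lower with both hairpins than with the RB hairpin alone by 2.03, while its interaction of -2.20 did not pass (limma adjusted p = 0.0582), and its second probe set differed by -0.16 and -0.32. RB1 transcripts binding the RBL2 probe set do not account for it, since RBL2 was 1.32 higher in shRB than in shLuc while RB1 fell. A single array does not, since the lowest shRB array was 1.67 above the highest array with both hairpins. An E2F7 hairpin that lowers RBL2 by itself does not, since RBL2 was 0.18 higher in shE2F7 than in shLuc. A fault of the 1 probe set stays open, as the second had means below log2 4 in every group (3.41 in shLuc, 3.81 in shRB), and so do regulation of RBL2 that needs E2F7 once RB is low and an off-target effect of both hairpins, neither tested.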

How the results depend on the processing

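The alternatives for called lists other than replication and mitosis, apart from the estimated correlation, were chosen after seeing the data. The replication and mitosis lists kept their direction and their side of the threshold under the alternatives tried, with the exceptions below, whose cause was not tested unless stated. Their medians with 1 array left out ran, for replication, from -2.15 to -2.02 in shLuc against growing, 1.59 to 1.80 in shRB, 0.26 to 0.34 in shE2F7 and 1.77 to 1.89 in shRB-E2F7 against shLuc, 0.14 to 0.27 against shRB, 1.42 to 1.77 against shE2F7, -0.27 to -0.02 against growing and -0.14 to -0.04 in the interaction. For mitosis they ran from -3.69 to -3.55, 0.54 to 0.65, 0.35 to 0.48, 1.62 to 1.78, 0.85 to 1.16, 1.15 to 1.39, -1.93 to -1.67 and 0.45 to 0.71, in the same order. Mitosis calls were lost with an estimated correlation in shRB (0.57, adjusted p = 0.105) and shE2F7 (0.42, 0.0619) against shLuc and in the interaction (0.54, 0.105). The replication call of shRB-E2F7 against shRB was lost with an estimated correlation (0.1633, adjusted p = 0.328), with the filter at log2 6 (0.1565, 0.0993), without shRB replicate 1 (0.1556, 0.131) and without shRB-E2F7 replicate 2 (0.1418, 0.0915). The uncalled replication test of shRB-E2F7 against growing turned its direction, though not its median, with the mean of all probe sets (-0.0869), without probe sets marked as matching several transcripts (-0.0992) and with fry (-0.1457).

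Counts of called genes depended on the genes tested, the fit and the arrays. With the filter at log2 6 they were 2386 (shLuc against growing), 1530 (shRB against shLuc), 1691 (shRB-E2F7 against shLuc), 1497 (against shE2F7) and 6 (interaction), since fewer genes were tested. With all 20860 probe sets tested the called probe sets, which are not counts of genes, were 6705 (shLuc against growing), 4039 (shRB), 25 (shE2F7) and 4546 (shRB-E2F7, these 3 against shLuc), 4031 (shRB-E2F7 against shE2F7) and 5237 (against growing), while the genes called on the probe set used for them fell to 3490, 2085, 12, 2404, 2120 and 2691 in that order. A fold of at least 2 as well, which keeps part of the called genes, left 2106 in shLuc against growing, 1028 in shRB and 1210 in shRB-E2F7 against shLuc, and in shRB-E2F7 330 against shRB, 1060 against shE2F7 and 1641 against growing. The fit of only the groups compared gave 23 in shE2F7 against shLuc, 307 in shRB-E2F7 against shRB and 21 in the interaction. The labels give replicates of different groups the same numbers without saying what they share. In 10 pairs of groups the correlation of the replicate differences ran from -0.146 to 0.585 with a median of 0.109, and 6 were over 0.1, so not every array went best with its own number and the numbers were not taken to pair the arrays. Values below 0 were those of shLuc with growing (-0.069) and with shRB (-0.146). Pairs without shLuc ran from 0.018 to 0.585, so variation shared by replicate number in those groups stays open. With the replicate block every called gene was kept and the counts were 28 in shE2F7 against shLuc, 1023 in shRB-E2F7 against shRB and 20 in the interaction. Array weights gave 224, 260 and 30, an intensity trend with robust eBayes gave 22 in shE2F7 against shLuc, and the mean of all probe sets gave 7 in the interaction. The weights were equal within each group, as they must be with 2 arrays and a mean per group, so this setting only reweighted the groups. They were highest for shLuc (2.987) and lowest for growing (0.548).

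With 1 array left out, the counts ran from 2182 to 3761 in shLuc against growing, 610 to 2781 in shRB, 1 to 20 in shE2F7 and 954 to 3059 in shRB-E2F7 against shLuc, 98 to 877 against shRB, 966 to 2784 against shE2F7, 1895 to 3187 against growing and 0 to 21 in the interaction. Of 5433 recomputed values of the genes named, 5230 kept their direction and side, 172 lost their call, 29 gained one and 2 reversed, both for the uncalled KRT18 in shLuc against growing (-0.16 without growing replicate 2 and -0.01 without shLuc replicate 1, with a highest value of 0.40). No called list reversed. Values below log2 4 are near background, so changes of genes that start there are limited by signal over background.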

Other observations

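The family of cornified envelope genes, its test and the test on replicate differences were chosen only after the result was seen. The correlation below of the 2 comparisons that add the E2F7 hairpin was also not among those planned. Of 37 genes listed for the cornified envelope, the outer layer of skin cells, 5 passed the filter, and 4 of them were higher in shLuc than in growing cells. That comparison joins the effects of Ras, the hairpin vector and selection. LCE3D rose by 7.50 in shLuc against growing, LCE2B by 5.82, IVL by 5.49 and CRCT1 by 3.82 (limma adjusted p of 8.48e-09, 1.75e-08, 7.54e-09 and 1.09e-07, n = 2 per group), from means below log2 4 in growing cells. All 4 fell with both hairpins against shLuc, by 4.37, 1.89, 3.37 and 2.49. LCE1E differed by 0.52 and -0.08.

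A shift of the whole family, rather than of LCE3D and IVL alone, was set to need at least 3 other members higher in shLuc and lower in shRB. Of the 3 others tested among 37 listed, 1 did so: CRCT1, which fell by 2.62 in shRB against shLuc. LCE2B differed by -0.12 there. LCE1E had means below log2 4 in every group, so only 2 other members could have passed, and the test could not tell.

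The changes of shE2F7 against shLuc and of shRB-E2F7 against shRB, which share no array, correlated across the 10144 genes at Pearson r = 0.274 and Spearman rho = 0.203, against -0.025 to 0.024 in 100 simulations without effects. Of the 14 genes called in the first, 13 had the same sign in the second, with 6 lower and 1 higher in both at an adjusted p under 0.05. These simulations take genes as independent. Differences between replicates, which hold no effect of a group, correlated from -0.167 to 0.047 for the same groups and from -0.487 to 0.584 over 60 values from all pairs of groups that share no array. The value of 0.274 lies above the range for the same groups and inside the range over all pairs. Both ends of the wider range came from pairs with the growing arrays, which neither comparison uses. Without the growing arrays the values ran from -0.228 to 0.273. The value with the groups and signs of the 2 comparisons was -0.167. Replicate differences also do not hold variation that both arrays of a group share. A shared effect of the E2F7 hairpin and variation that arrays share therefore cannot be told apart here.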
